A study of Homo sapiens with 22 samples.

How the data were processed

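Poly-A RNA was sequenced from untreated and osimertinib-resistant PC9, HCC827 and H1975 cells and from PC9 cells treated with osimertinib for 28, 35 or 56 days. Per the submitters' processing notes, reads were aligned to GRCh38 with STAR (version 2.7.7a) and assigned to genes with featureCounts (Subread, version 2.0.3). The values deposited by the authors are raw counts per gene symbol, in 1 table of 56609 rows and 22 columns, without normalisation. The strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Counts of paralogs (protocadherin, pregnancy glycoprotein, HLA, zinc finger and AKR1C genes), of overlapping genes and of antisense genes are therefore less certain. The drug dose of the time course is not in the labels.

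The 2 day 0 columns were checked against untreated PC9 replicates 1 and 2 and held the same count in every row. They were treated as the same libraries, so 20 distinct libraries were analysed in place of the 22 planned, and day 0 could not be compared with untreated PC9. The overlap of day 56 with PC9-OR, planned as a comparison with different untreated libraries, has shared controls for the same reason. Total counts, in units of 1e6, were 26.1, 23.7 and 23.5 in PC9, 23.9, 25.8 and 23.8 in PC9-OR, 25.6 and 20.7 in HCC827, 18.7 and 19.2 in HCC827-OR, 16.3 and 17.6 in H1975, and 19.4 and 37.8 in H1975-OR. Libraries of the time course held 20.0 and 24.6 on day 28, 23.3 and 24.9 on day 35, and 17.6 and 23.4 on day 56.

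Counts were analysed in R (version 4.3.3) with edgeR (version 4.0.16). Genes with low counts were removed with filterByExpr over the groups, which left 20835 genes; the 35774 removed held 0.0549% of the counts. Library sizes were scaled by TMM, and quasi-likelihood models with robust estimation were fitted to group means, without a replicate block. The resistance comparisons used a fit with 11 residual degrees of freedom, and the time course, with PC9 replicates 1 and 2 as day 0, a fit with 10. Standard errors of log2 changes were the absolute change over the square root of the F statistic. The common biological coefficient of variation was 0.218. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each of 12 contrasts, and calls with at least a 2-fold change were also counted. Contrasts were each resistant line against its parent, each time point against day 0, each pair of time points, and the difference in resistance effect between each pair of lines. Where a group had 0 reads, the bound on the fold used 3 counts over the group; with 1 to 3 reads, the ratio is given with a counting interval at a level of 0.95.

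Before the data were examined, 26 gene lists (513 genes, of which 473 were tested) were fixed, as was the rule for named genes. The lists were receptor tyrosine kinases and ligands, ERK pathway output, oncogenes amplified in lung adenocarcinoma, the MET neighbourhood, epithelial, mesenchymal, alveolar and lung lineage, squamous and basal, and neuroendocrine genes, YAP/TEAD targets, mitosis and proliferation, DNA replication, interferon response, antigen presentation, cohesin and CTCF, chromatin regulators, the BCL2 family, NRF2 targets, drug efflux and aldehyde dehydrogenases, cholesterol synthesis, hypoxia and glycolysis, the unfolded protein and integrated stress response, NF-kB targets and inflammatory genes, and fibroblast, blood cell and endothelial markers. Lists with at least 5 tested members (24 lists) were tested with camera in limma (version 3.58.1), two-sided, at a preset correlation of 0.01, and again with an estimated correlation and with fry. EGFR, MET, ERBB2, AXL and METTL7A were named in each main comparison. Also named were the 6 genes with the highest and the 6 with the lowest log2 fold change in each resistant line and on day 56 (at least 10 CPM in the higher group, no overlap between groups, no unnamed or non-coding loci). Up to 4 members per list were named by smallest adjusted p, as were up to 10 genes per direction shared by all 3 lines or by all time points and PC9-OR, and up to 4 genes and any listed oncogene per region. Some genes are not reported here.

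Gene positions came from GENCODE 29 on GRCh38, in which 54266 of the 56609 symbols and 20323 of the tested genes had a place. Windows of 20 neighbouring tested genes (step 5) passed when the absolute median log2 fold change was at least 0.5 and above the largest window median in 95% of 1000 shuffles of the genes; overlapping windows of 1 sign were merged. Overlaps between gene lists were set beside the count for independent lists, and comparisons with shared controls also beside 10 simulations without any effect. The count for independent lists takes every tested gene as equally likely to be called.

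The pipeline was tested on simulated data, with recovery counted among changed genes at 1 CPM or more in the untreated group. Changes of 2-fold were recovered in 61.1% of these in the PC9-OR comparison and in 19.6% to 34.8% in the others. Changes of 4-fold were recovered in 83.3% to 98.9%, and 2.06% to 6.19% of calls were false. Far fewer genes were changed in the simulations than were called in the data, and each gene had the same spread in every group. The shares recovered and false in the real tests may therefore differ. Alternatives were relative log expression (RLE) size factors within edgeR, no filter on low counts, a replicate block and the DESeq2 (version 1.42.0) Wald test. Others were fits of only the compared libraries, windows of 10 or 40 genes, and leaving out each library in turn. After the data were seen, 3 more were added: untreated replicate 3 alone as the control of PC9-OR, all 3 untreated PC9 libraries as the control of the time course, and counts with each library's trends in GC content and transcript length removed.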

Results

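Gene expression was measured by RNA sequencing in 3 established human lung adenocarcinoma cell lines driven by mutant EGFR: PC9, HCC827 and H1975. Each line was sequenced untreated and as an osimertinib-resistant derivative (PC9-OR, HCC827-OR and H1975-OR). Osimertinib is an inhibitor selective for mutant EGFR. The derivatives came from the parental cells by chronic exposure and were grown in 1 µM of the drug. Each resistant line under drug was thus compared with an untreated parent, so acquired resistance and the presence of drug cannot be told apart. PC9 cells were also sequenced after 28, 35 and 56 days of osimertinib. No untreated sample was labelled with those days, so drug and time in culture cannot be told apart in the time course. The count table held 22 columns. Both day 0 columns of the time course repeated untreated PC9 replicates 1 and 2, with 0 of 56609 genes different, so they were counted as the same samples and 20 distinct libraries remained. A comparison of day 0 with untreated PC9 could therefore not be made. Untreated PC9 and PC9-OR had 3 libraries each and every other group had 2. Total counts ranged from 16276697 to 37805600 per library. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

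Of the libraries, 2 stood apart from the others of their group. Untreated PC9 replicate 1 had 19702 genes with at least 1 read at a total of 26118496 counts, against 23657 and 23312 genes in replicates 2 and 3. H1975-OR replicate 2 had the highest total, and mitochondrial transcripts made up 5.53% of its counts against 3.28% in replicate 1. Levels are TMM-normalised counts per 1e6 (CPM), as mean ± SD over n libraries, and changes are log2 fold changes with their SE. Genes called higher or lower had an edgeR adjusted p under 0.05. For each gene named as changed, the libraries of the 2 groups did not overlap. Where 1 group had no reads, the fold is a bound set at 3 reads over the group, and bounds and intervals cover counting error only.

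The first comparison asked how stably resistant PC9 cells differed from their untreated parent. MET, a receptor tyrosine kinase that can bypass EGFR, fell from 421 ± 135 to 26.2 ± 0.659 CPM in PC9-OR (n = 3 and 3; log2 change -4.01, SE 0.23, adjusted p = 2.50e-10). AXL, another receptor tyrosine kinase, was 232-fold lower at 1.37 ± 0.357 against 318 ± 28.3 CPM. EGFR was lower at 383 ± 11.1 against 570 ± 111 CPM (log2 change -0.58, adjusted p = 0.0237), a call that ended without PC9 replicate 1 (adjusted p = 0.0756) or without any single PC9-OR library (adjusted p 0.0563 to 0.0725), and with PC9 replicate 3 as the only control (adjusted p = 0.424). ERBB2 (log2 change 0.12, adjusted p = 0.698) and METTL7A, a membrane-bound methyltransferase (log2 change 0.12, adjusted p = 0.775), did not pass the test. Over 20835 tested genes, 4050 were higher and 4814 lower, of which 2614 and 3198 changed at least 2-fold; a fit of these 6 libraries alone called 2697 higher.

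The largest changes in PC9-OR included genes without reads in 1 group. SEMA5A, an axon guidance ligand, was at 164 ± 7.64 CPM with 1 read in untreated PC9, an 11590-fold difference with a counting interval of 2080 to 457810. C5orf38, with 0 reads in untreated PC9, was at least 896-fold higher, SIPA1L2 at least 626-fold and LONRF2 at least 594-fold. The metalloprotease ADAMTS12 had 0 reads in PC9-OR and was at least 3265-fold lower than its 146 ± 32.5 CPM in PC9. ADGRF5 was at least 905-fold lower, GCNT2 at least 776-fold and EMB at least 610-fold. CEACAM6, a surface adhesion molecule, went from 873 ± 214 to 0.121 ± 0.133 CPM. GDA, guanine deaminase, had 1 read in PC9-OR, a ratio of 8.78e-05 to PC9 with a counting interval of 2.22e-06 to 4.89e-04.

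Transcriptional targets of ERK signalling were largely lower in PC9-OR: 13 of 20 fell and 1 rose, the same counts as when adjusted over the list alone. IER3 (log2 change -3.48), SPRY1 (-4.55), ETV1 (-6.95) and PHLDA1 (-2.02) had the smallest adjusted p in that list. The list test (limma's camera) gave an adjusted p = 0.000509, and adjusted p = 0.291 with an estimated correlation. Of 9 genes around MET on chromosome 7, 7 fell and 0 rose (8 lower adjusted over the list alone), among them CAV1 (-1.67) and ST7 (-1.06; -0.68 without PC9 replicate 1, and -0.48, adjusted p = 0.139, with replicate 3 as the only control); the list had an adjusted p = 0.00531, and adjusted p = 0.388 with an estimated correlation. Epithelial genes rose in 12 of 25 cases and fell in 2 (12 and 3 adjusted over the list alone), with the keratin KRT19 at 7484 ± 236 against 1630 ± 376 CPM and KRT18, ESRP2 and KRT8 higher by 1.54, 1.81 and 2.31. That list had an adjusted p = 0.0054, and adjusted p = 0.388 with an estimated correlation. Mesenchymal genes were mixed, with 5 higher and 10 lower of 21 (6 and 10 adjusted over the list alone; adjusted p = 0.0559): TGFBI fell by 5.87 and NT5E by 5.61, whereas FN1 rose by 3.33 and SPARC by 4.18. Untreated PC9 replicate 1, the library with the fewest detected genes, is among the controls of each of these groups.

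Lists of inflammatory, interferon and antigen presentation genes were called lower in PC9-OR. Of 21 NF-kB target and inflammatory genes, 12 fell and 3 rose, also when adjusted over the list alone, with LCN2 at 0.568 ± 0.22 against 180 ± 43 CPM (adjusted p = 0.0475 for the list, and adjusted p = 0.291 with an estimated correlation). Interferon response genes fell in 14 of 27 cases and rose in 5 (15 and 5 adjusted over the list alone), OAS1 by a log2 change of -3.39; the list had an adjusted p = 0.0475, and adjusted p = 0.494 with an estimated correlation. Antigen presentation genes fell in 9 of 20 cases with 0 higher, on either adjustment, including CD74 (-7.50) and ERAP2 (-3.91); the list had an adjusted p = 0.0283, and adjusted p = 0.636 with an estimated correlation. All 3 list calls ended without PC9 replicate 3 (adjusted p = 0.083 each), the NF-kB call also without PC9-OR replicate 1 (0.0505) and the interferon call with a replicate block (0.068). Of the drug efflux and aldehyde dehydrogenase genes, 8 of 15 fell and 3 rose, also when adjusted over the list alone, with ALDH3A1 at 0.242 ± 0.313 against 982 ± 397 CPM (adjusted p = 0.0172, and adjusted p = 0.209 with an estimated correlation). In the BCL2 family, 6 of 16 genes rose and 1 fell, on either adjustment (adjusted p = 0.0479, and adjusted p = 0.388 with an estimated correlation). The pro-apoptotic BCL2L11 reached 119.7 ± 2.54 against 18.6 ± 1.32 CPM and HRK 9.17 ± 1.11 against 0.354 ± 0.174, while BIK, also pro-apoptotic, fell by 2.78. The BCL2 family call ended without PC9 replicate 1 (adjusted p = 0.242), PC9-OR replicate 1 (0.0504) or PC9-OR replicate 3 (0.0567), and with a replicate block (0.0544).

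Since the series concerns amplified oncogenes, neighbouring genes were scanned for shared shifts along the genome (GRCh38). PC9-OR had 3 regions of higher and 15 of lower expression by window medians, which also include genes that did not pass the test. On chromosome 3, from 9649433 to 12769457, 42 of 50 tested genes rose and 3 fell; the region holds IL17RE, an interleukin receptor subunit at 771 ± 45.5 against 10.9 ± 5.73 CPM. On chromosome 22, from 16869478 to 28679865, 155 of 200 genes rose and 3 fell. That region includes the adaptor gene CRKL (335 ± 12.7 against 80.6 ± 4.61 CPM, log2 change 2.05, adjusted p = 2.36e-09). On chromosome 20, from 58594417 to 62068437, 19 of 25 genes rose, with SYCP2 at 68.6 ± 5.14 against 1.29 ± 0.787 CPM. The longest run of lower genes was on chromosome 19, from 19668796 to 29617237, with 44 of 80 lower and 3 higher. With windows of 40 genes, 31 regions passed in place of 18. DNA copy number was not measured.

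The second comparison asked the same of HCC827. MET rose 6.64-fold, from 980.2 ± 43 to 6531 ± 470 CPM (n = 2 and 2; log2 change 2.74, SE 0.26, adjusted p = 1.35e-06). EGFR fell from 6849 ± 62.2 to 2776 ± 129 CPM (log2 change -1.30, SE 0.24, adjusted p = 0.00104). AXL was 16.1-fold lower (2.19 ± 0.164 against 35.2 ± 3.25 CPM) and METTL7A 49-fold lower (0.305 ± 0.0348 against 14.6 ± 4.12 CPM). ERBB2 (log2 change -0.07, adjusted p = 0.943) did not pass the test. In all, 1479 genes were higher and 1689 lower, with 967 and 1237 changed at least 2-fold. These counts depended on the libraries used: leaving out any 1 of the 4 gave 670 to 831 higher and 803 to 1189 lower, and a fit of these 4 libraries alone gave 4395 and 4627.

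**Figure D1:**
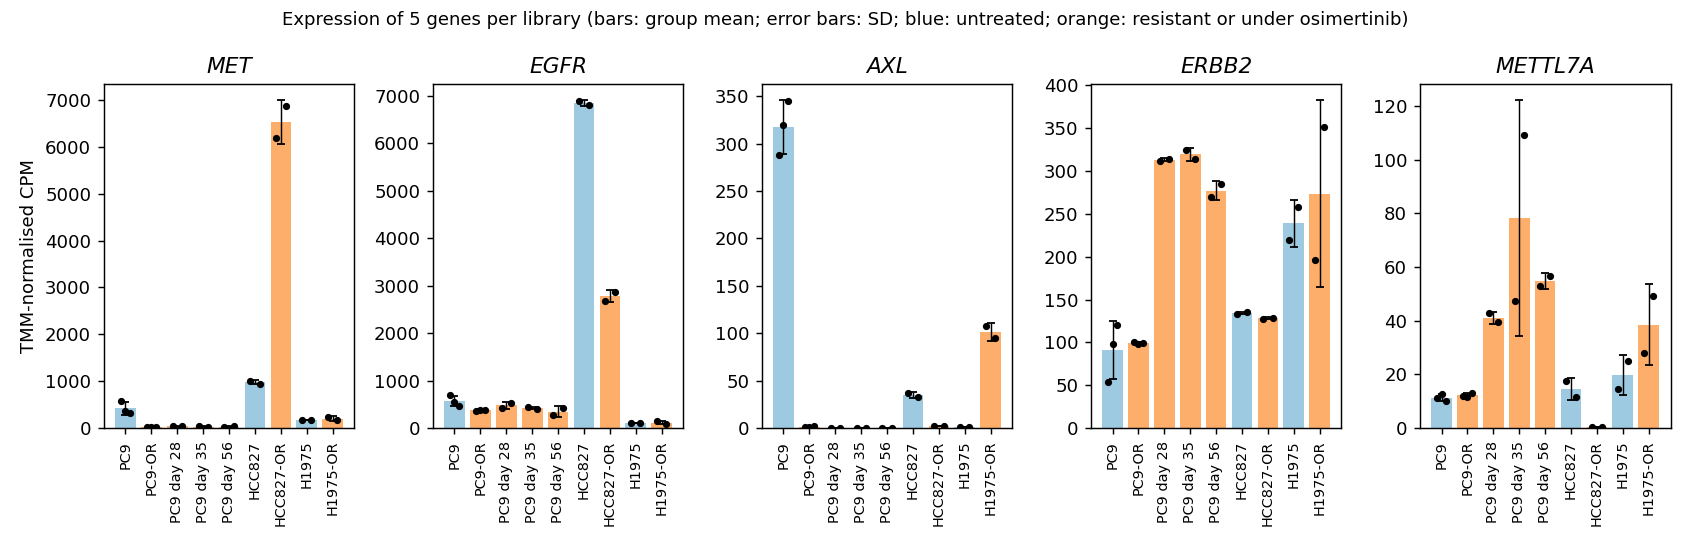
TMM-normalised CPM (y axis, linear) of 5 genes in each group (x axis); bars are group means, error bars SD, and points single libraries. MET is highest in HCC827-OR (6531 CPM), and AXL is high in untreated PC9 (318 CPM) and in H1975-OR (101 CPM).

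The largest changes in HCC827-OR also included genes without reads in 1 group. S100A9, a calcium-binding alarmin, was at 559 ± 62.5 CPM with 0 reads in HCC827, at least 8286-fold higher. The defensin DEFB4A reached 659 ± 44.9 against 0.288 ± 0.0487 CPM, and the serpin SERPINB4 was 438-fold higher. TNIP3, an inhibitor of NF-kB signalling, was at least 945-fold higher and SPRR2F, a cornified envelope protein, at least 223-fold. NCALD had 2 reads in HCC827 and was 557-fold higher with a counting interval of 154 to 4607. The synaptotagmin SYT14 (at least 274-fold) and the transcription factor MEF2C (at least 167-fold) had 0 reads in HCC827-OR. BICC1 was 343-fold and ALPP 344-fold lower. ADAMTS6 and PRICKLE1 had 3 reads each in HCC827-OR, at ratios of 0.004 (interval 8.23e-04 to 0.0117) and 0.00543 (interval 0.00112 to 0.0159) to HCC827.

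In HCC827-OR, 5 gene lists were called both with the preset and with an estimated correlation. NF-kB target and inflammatory genes rose in 13 of 21 cases and fell in 1 (13 and 2 adjusted over the list alone), with LCN2 at 3817 ± 225 against 30.4 ± 0.513 CPM, CXCL1 up by 6.11, IL1B by 3.88 and SOD2 by 3.22 (adjusted p = 1.96e-07, and adjusted p = 0.00481 with an estimated correlation). Interferon response genes rose in 18 of 27 cases with 0 lower (19 adjusted over the list alone), led by IFI27 (434 ± 1.64 against 19 ± 0.739 CPM), OAS2 (78.1 ± 12.5 against 1.57 ± 0.287 CPM), IFI6 and MX1 (adjusted p = 3.28e-11, and adjusted p = 0.0157 with an estimated correlation). Hypoxia and glycolysis genes rose in 13 of 21 cases with 0 lower (15 adjusted over the list alone), including PFKFB3 (2.54), PFKFB4 (2.45), BNIP3 (1.33) and NDRG1 (524 ± 11.2 against 101 ± 5.19 CPM); the adjusted p = 1.25e-10, and adjusted p = 0.0157 with an estimated correlation. YAP/TEAD target genes, readouts of the Hippo pathway, fell in 15 of 22 cases and rose in 1 (16 and 1 adjusted over the list alone), including CYR61 (260.3 ± 41.6 against 3251 ± 16.6 CPM), ANKRD1 (-5.08) and F3 (-2.93), with an adjusted p = 1.25e-10, and adjusted p = 0.0162 with an estimated correlation. Alveolar and lung lineage genes rose in 8 of 17 cases and fell in 2 (10 and 3 adjusted over the list alone), with SLC34A2 up by 6.42, CEACAM6 by 4.91 and LPCAT1 by 1.93, and GATA6 lower (-1.36); the adjusted p = 0.00105, and adjusted p = 0.0349 with an estimated correlation.

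Other list calls in HCC827-OR were lost with an estimated correlation. Antigen presentation genes rose in 13 of 20 cases with 0 lower (17 adjusted over the list alone), including PSMB9 (1.60) and TAP1 (1.40), with an adjusted p = 2.12e-09, and adjusted p = 0.086 with an estimated correlation. DNA replication genes rose in 7 of 30 cases with 0 lower, on either adjustment, including CCNE2 (2.32) and MCM7 (1.45), with an adjusted p = 3.39e-05, and adjusted p = 0.761 with an estimated correlation. Of the unfolded protein and integrated stress response genes, 7 of 21 fell and 1 rose (10 and 1 adjusted over the list alone), including ATF3 (-1.80) and HERPUD1 (-1.35), with an adjusted p = 0.0364, and adjusted p = 0.825 with an estimated correlation; this call ended without HCC827 replicate 1 (0.0559) or HCC827-OR replicate 1 (0.0701). ERK targets went both ways, 4 higher and 4 lower of 20 (6 and 5 adjusted over the list alone; adjusted p = 0.332), with the ERK phosphatase DUSP6 up by 2.59 and the early response factor EGR1 down (-2.32). Of the 9 genes around MET, 4 rose and 0 fell, on either adjustment: MET, CAPZA2 (857 ± 46.5 against 125 ± 6.12 CPM, log2 change 2.78), ST7 (2.93) and TES (1.72). That list had an adjusted p = 7.91e-05, and adjusted p = 0.109 with an estimated correlation.

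Along the genome, HCC827-OR had 4 regions of higher and 6 of lower expression. One ran from 113116718 to 120750331 on chromosome 7 and held MET (116672390 to 116798386), with 8 of 20 tested genes higher and 0 lower. Another, on chromosome 1 from 151841877 to 153631360, held the S100 and SPRR gene clusters, with 14 of 35 genes higher and 2 lower. Without either HCC827-OR library, 6 regions passed in place of 10. Windows passed on the median fitted change of all their genes, so a region can hold few called genes. A lower region on chromosome 19, from 42401507 to 43527244, had 2 genes higher and 2 lower of 20.

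**Figure D2:**
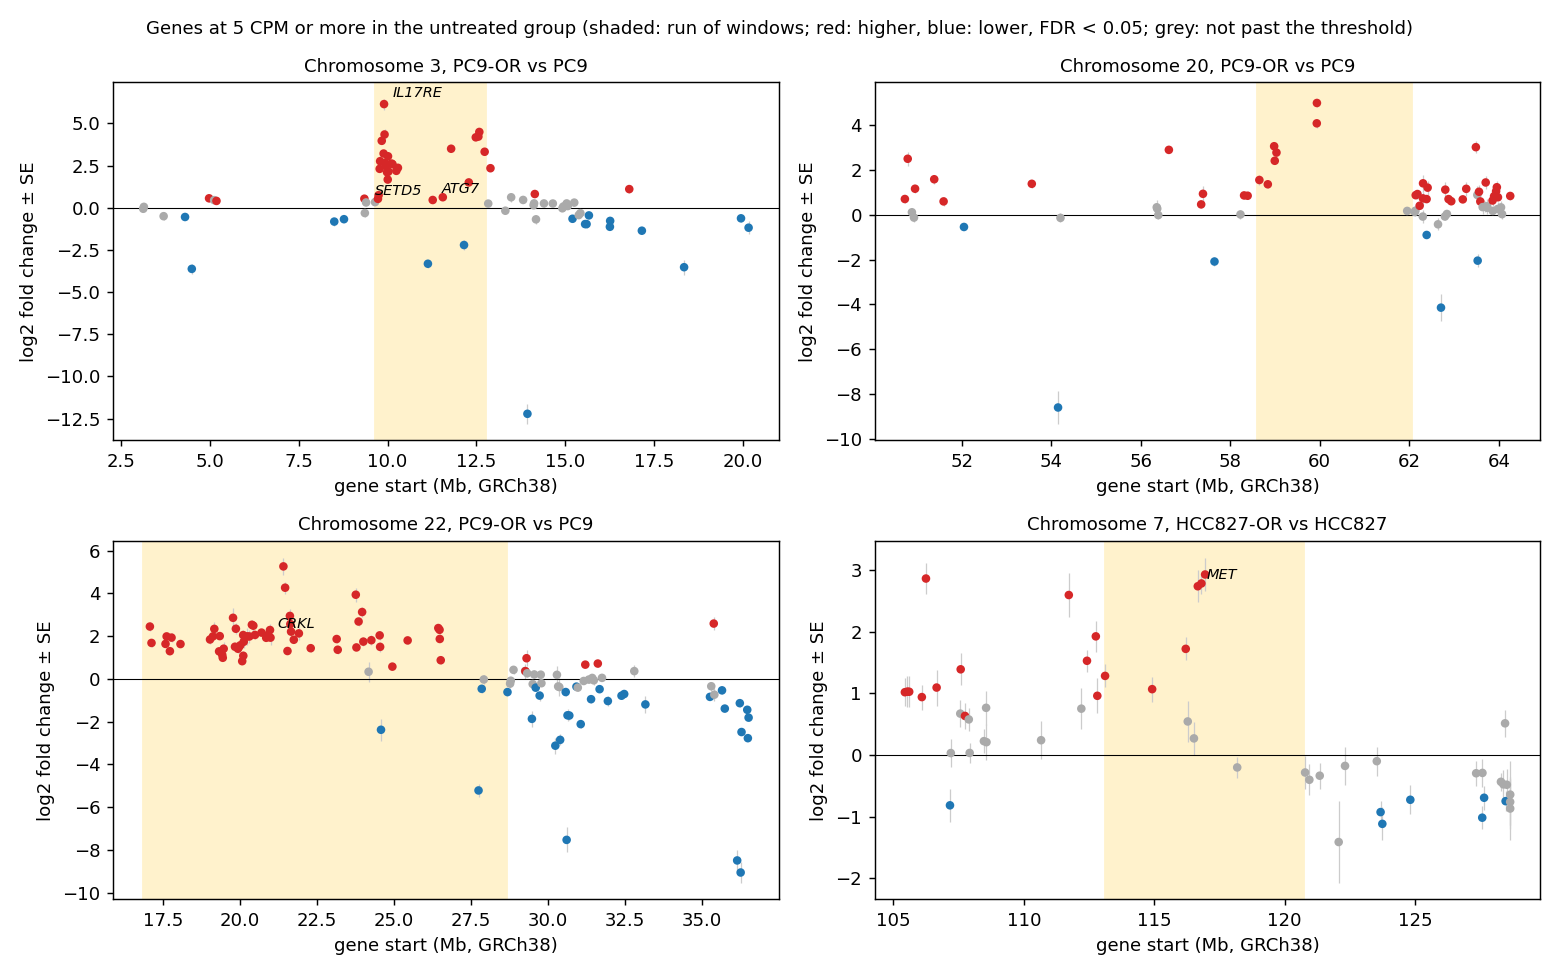
Log2 fold change with SE (y axis) of genes with at least 5 CPM in the untreated group, by gene start in Mb on GRCh38 (x axis), in and beside 4 runs of higher genes (shaded); red and blue points passed the test as higher and lower, grey points did not. On chromosome 22, 60 of 65 such genes in the run rose in PC9-OR, and on chromosome 7, 6 of 9 rose in HCC827-OR.

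In H1975, the third comparison, AXL rose 87.3-fold in the resistant cells, from 1.13 ± 0.142 to 101 ± 9.39 CPM (n = 2 and 2; log2 change 6.47, SE 0.35, adjusted p = 3.04e-09). EGFR (log2 change 0.02, adjusted p = 0.998), MET (0.28, adjusted p = 0.492), ERBB2 (0.20, adjusted p = 0.690) and METTL7A (0.97, adjusted p = 0.0525) did not pass the test. METTL7A passed without H1975-OR replicate 1 (adjusted p = 0.0182) or H1975 replicate 2 (0.04). ERBB3, a partner of EGFR, fell from 203 ± 22.8 to 39.5 ± 9.07 CPM, whereas the EGFR ligand HBEGF rose to 83 ± 1.86 from 4.88 ± 2.09 CPM and NRG1, a ligand of ERBB3, to 33.9 ± 23.9 from 3.44 ± 1.41 CPM. In all, 2030 genes were higher and 2201 lower, with 1341 and 1549 changed at least 2-fold. Without H1975 replicate 1 the counts were 1018 and 1363, without H1975 replicate 2 1079 and 1448, and a fit of these 4 libraries alone gave 901 and 1212.

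Among the largest changes in H1975-OR were genes without reads in H1975. PLCB4, a phospholipase C, was at 53.6 ± 7.65 CPM with 0 reads in H1975 and so at least 670-fold higher, TENM2 at least 391-fold, the proteoglycan SDC2 at least 291-fold and the smooth muscle calponin CNN1 at least 148-fold. The collagen COL12A1 reached 211 ± 69.9 against 0.156 ± 0.0106 CPM, and PTPRG was 985-fold higher. The stem cell factor SOX2 fell from 129 ± 5.74 to 0.15 ± 0.0262 CPM, and its relative SOX21 was 483-fold lower. HDGFL3 was at least 411-fold lower. The tyrosine kinase SYK had 2 reads in H1975-OR, a ratio of 4.82e-04 (interval 5.84e-05 to 0.00174), ST6GALNAC1 was 518-fold lower and the ferroxidase CP 372-fold. All 23 reads of CP in the resistant cells came from replicate 2, the library with the highest total, and without it the fitted log2 change was -14.49.

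The epithelial gene list was called lower and the mesenchymal gene list higher in H1975-OR, and neither was called with an estimated correlation. Of 25 epithelial genes, 17 fell and 2 rose (19 and 2 adjusted over the list alone), among them ESRP1 (25.2 ± 1.73 against 184 ± 4.85 CPM), GRHL2 (-2.57), RAB25 (-2.81) and MARVELD3 (-1.81); the adjusted p = 1.68e-08, and adjusted p = 0.0621 with an estimated correlation. Of 21 mesenchymal genes, 12 rose and 1 fell (14 and 1 adjusted over the list alone), with VIM at 367 ± 36.7 against 6.87 ± 2.67 CPM, ZEB1, a repressor of epithelial genes, up by 4.42 and SPARC by 3.39; the adjusted p = 2.48e-07, and adjusted p = 0.0515 with an estimated correlation. YAP/TEAD target genes rose in 15 of 22 cases and fell in 2 (17 and 2 adjusted over the list alone), with ANKRD1 at 72.8 ± 22.1 against 0.175 ± 0.171 CPM, CCDC80 up by 4.15 and F3 by 2.98; the adjusted p = 3.25e-07, and adjusted p = 0.0621 with an estimated correlation. Alveolar and lung lineage genes fell in 6 of 17 cases and rose in 1 (7 and 1 adjusted over the list alone), with FOXA1 (-3.27), FOXA2 (-3.94) and LAMP3 (-4.12) lower; the adjusted p = 0.0144, adjusted p = 0.107 with an estimated correlation, and 0.117 without H1975-OR replicate 1. The fibroblast marker genes COL1A1, COL3A1 and PDGFRB rose in the same comparison, the latter 2 from 0 reads in H1975. The call of COL1A1 (log2 change 1.65) ended without H1975 replicate 1 (adjusted p = 0.0501) or H1975-OR replicate 2 (0.0589), and that of COL3A1 in a fit of these 4 libraries alone (0.0597).

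Lists of signalling, stress and metabolic genes were also called in H1975-OR. ERK targets fell in 9 of 20 cases and rose in 1, on either adjustment, including EGR1 (-5.04), DUSP6 (-2.99), DUSP5 (-2.44) and PHLDA1 (-2.18); the adjusted p = 0.000366, and adjusted p = 0.174 with an estimated correlation. Interferon response genes fell in 14 of 27 cases with 0 higher (17 lower and 1 higher adjusted over the list alone), including OAS1 (-2.50), IFIH1 (-2.38) and USP18 (-2.24); the adjusted p = 5.10e-06, and adjusted p = 0.0825 with an estimated correlation. NRF2 target genes fell in 12 of 23 cases and rose in 1 (13 and 1 adjusted over the list alone), with ABCC2 (-3.80) and HMOX1 (-3.19) lower and the ferritin chain FTL higher (1.61); the adjusted p = 0.000194, and adjusted p = 0.061 with an estimated correlation. Unfolded protein and integrated stress response genes fell in 7 of 21 cases and rose in 1 (9 and 1 adjusted over the list alone), including TRIB3 (-2.42) and PHGDH (-2.26); the adjusted p = 0.00421, adjusted p = 0.508 with an estimated correlation, and 0.176 without H1975-OR replicate 1. Cholesterol synthesis genes fell in 7 of 24 cases and rose in 2, on either adjustment, including FDPS (-1.29) and SQLE (-1.28); the adjusted p = 0.0208, adjusted p = 0.476 with an estimated correlation, 0.109 without H1975 replicate 2 and 0.244 without H1975-OR replicate 2. Of 21 hypoxia and glycolysis genes, 7 rose and 2 fell, on either adjustment, including ADM (4.03) and LDHA (1.25); the adjusted p = 0.0145, adjusted p = 0.381 with an estimated correlation, 0.0617 without H1975 replicate 2 and 0.0567 without H1975-OR replicate 2.

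Mitosis and DNA replication genes gave different results with either resistant H1975 library left out. Of 25 mitosis and proliferation genes, 0 rose and 0 fell by the edgeR test, on either adjustment, while the list test gave an adjusted p = 0.0144 for lower expression, and adjusted p = 0.746 with an estimated correlation. Without H1975-OR replicate 2 the same list was higher (adjusted p = 0.00209), and without H1975-OR replicate 1 TOP2A, a topoisomerase of dividing cells, was lower by a log2 change of -1.99. The DNA replication list did not pass (0 of 30 changed, adjusted p = 0.421), but was higher without H1975-OR replicate 2 (adjusted p = 1.96e-06) and lower without replicate 1 (adjusted p = 1.05e-11). Along the genome, H1975-OR had 4 regions of higher and 9 of lower expression, 6 in all without H1975-OR replicate 2 and 4 with windows of 10 genes. Lower regions lay on chromosomes 1, 2 and 8, such as 156212993 to 156816862 on chromosome 1 (22 of 30 genes lower) and 81280363 to 93819234 on chromosome 8 (21 of 45 lower).

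The 3 resistant lines were then compared with each other through the difference of their resistant-minus-parental changes. The change in MET was higher in HCC827 than in PC9 by 6.74 on the log2 scale (SE 0.35, adjusted p = 3.42e-10) and higher than in H1975 by 2.46 (SE 0.35, adjusted p = 7.08e-05). The change in AXL was higher in H1975 than in PC9 by 14.33 (SE 0.48, adjusted p = 8.10e-12). In total 6205 genes differed between HCC827 and PC9, 6687 between H1975 and PC9 and 3932 between HCC827 and H1975. Of the last, 2056 had a lower change in HCC827, or 1360 without HCC827-OR replicate 1. Across genes, which are not independent replicates, log2 fold changes of the lines had Pearson correlations of -0.02 (PC9 and HCC827), 0.04 (PC9 and H1975) and -0.13 (HCC827 and H1975).

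A small set of genes moved the same way in all 3 resistant lines. NDRG1, a gene induced by hypoxia, rose by 1.89 in PC9-OR, 2.37 in HCC827-OR and 1.91 in H1975-OR, and ADM, which encodes the vasodilator adrenomedullin, by 2.05, 2.44 and 4.03. The tubulin gene TUBA1A rose by 1.34, 2.33 and 1.37, and the integrin gene ITGB2 was lower in each line (-4.25, -2.42 and -2.16; the last was -3.48 without H1975-OR replicate 2 and did not pass in a fit of the 4 H1975 libraries alone, adjusted p = 0.0964). In all, 52 genes were higher in all 3 lines, where independent lists would share 28.0, and 85 were lower, where they would share 41.2. The higher count was 31 without HCC827 replicate 1, 32 without HCC827 replicate 2 and 33 without H1975 replicate 1. The lower count was 46 without HCC827-OR replicate 1, and 51 without HCC827-OR replicate 2 or without HCC827 replicate 1. DESeq2 called 81 genes higher in all 3 lines. The count for independent lists takes every gene as equally likely to be called, so an excess need not mean a shared response. HCC827-OR and H1975-OR shared 175 higher and 230 lower genes, against 144 and 178 for independent lists, although their changes had a correlation of -0.13.

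The time course asked how PC9 cells changed over weeks of osimertinib. MET was lower at each time point, at 37.5 ± 5.23, 28.5 ± 7.03 and 29.5 ± 5.58 CPM on days 28, 35 and 56 against 473 ± 142 on day 0 (n = 2 per group; day 56 log2 change -4.002, SE 0.25, adjusted p = 3.16e-09). AXL had 5, 6 and 0 reads on days 28, 35 and 56, the last at least 4191-fold lower than its 304 ± 22.1 CPM on day 0. ERBB2, the partner receptor of EGFR, rose to 313 ± 1.71, 319.7 ± 7.67 and 277 ± 10.8 CPM from 76 ± 30.7 (day 56 log2 change 1.87, adjusted p = 9.57e-06; 1.14 with trends in GC content and length removed). METTL7A rose to 41.2 ± 2.26, 78.3 ± 43.9 and 54.8 ± 2.88 CPM from 11.9 ± 0.941 (day 56 log2 change 2.20, adjusted p = 8.04e-05). EGFR changed by -0.38 (adjusted p = 0.171), -0.56 (adjusted p = 0.0465) and -0.83 (adjusted p = 0.00538). The day 35 call ended without day 35 replicate 1 (0.101), day 35 replicate 2 (0.168) or day 0 replicate 1 (0.227), and the day 56 call without day 56 replicate 1 (0.0975).

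On day 56, CAPN6, a calpain-like protein, was at 270.3 ± 73.2 CPM with 0 reads on day 0, at least 4426-fold higher. SEMA5A was at least 3905-fold higher, FSTL4 at least 1323-fold and IRX6 at least 1112-fold. TRBC2, a T-cell receptor constant region gene, was at least 797-fold lower, SLCO1B3 at least 292-fold, DMBT1 at least 268-fold, and the zinc finger genes ZNF738 and ZNF43 at least 233-fold and 202-fold. Higher and lower genes numbered 5904 and 5357 on day 28, 6183 and 5583 on day 35, and 6171 and 5605 on day 56; at least 2-fold changes numbered 4662 and 3694, 4988 and 3952, and 5023 and 3936. Fits of only the libraries compared gave 3030 and 3055, 3304 and 3220, and 3505 and 3291.

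Genes of cell division fell almost as a whole list. Of 25 mitosis genes, 24, 25 and 25 were lower on days 28, 35 and 56 with 0 higher, also when adjusted over the list alone. TOP2A was at 28.5 ± 2.77 CPM on day 56 against 429.6 ± 109 on day 0, and BUB1B, a spindle checkpoint kinase, was lower by -4.63. The list test gave adjusted p = 7.12e-07, 4.54e-09 and 9.68e-10 by day, and adjusted p = 0.542, 0.459 and 0.367 with an estimated correlation. Of 30 DNA replication genes, 27, 29 and 29 fell with 0 higher (29 on each day adjusted over the list alone), including POLA1 (-2.80), MCM6 (-3.04) and MCM3 (-3.41) on day 56. Its adjusted p was 2.30e-07, 4.00e-09 and 9.34e-10, and adjusted p = 0.542, 0.459 and 0.367 with an estimated correlation. Genes of cohesin, the ring that holds sister chromatids, and CTCF fell in 12 of 15 cases and rose in 1 on each day, on either adjustment, with SMC1A at 37.6 ± 6.09 against 376 ± 30.3 CPM on day 56. The adjusted p was 0.00546, 0.00178 and 0.000502, and adjusted p = 0.542, 0.459 and 0.367 with an estimated correlation. ERK targets fell in 14 of 20 cases and rose in 2 on each day, on either adjustment, including PHLDA1 (-6.59), ETV5 (-6.40), DUSP6 (-5.54) and SPRED1 (-4.41) on day 56. The adjusted p was 3.72e-05, 2.03e-05 and 7.18e-06, and adjusted p = 0.4, 0.415 and 0.367 with an estimated correlation. Untreated replicate 1, with the fewest detected genes, is 1 of the 2 day 0 libraries in each of these tests.

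The epithelial gene list was called higher and the mesenchymal gene list lower on each day, and neither was called with an estimated correlation. Of 25 epithelial genes, 17, 17 and 18 rose and 2, 3 and 3 fell by day, on either adjustment. ESRP2, SPINT1 and KRT19 rose by 2.22, 2.74 and 1.78 on day 56, and by 1.33, 1.79 and 0.47 with trends in GC content and length removed, where KRT19 no longer passed (adjusted p = 0.0643). The list had an adjusted p of 0.000424, 0.00145 and 0.00277, and adjusted p = 0.402, 0.432 and 0.367 with an estimated correlation. Of 21 mesenchymal genes, 11, 13 and 15 fell and 5, 4 and 4 rose (13, 13 and 15 lower adjusted over the list alone), including VIM (-5.66), SPARC (-5.18) and TGFBI (-3.57), while FN1 rose by 2.18. Its adjusted p was 0.0118, 0.00457 and 0.00355, and adjusted p = 0.402, 0.432 and 0.367 with an estimated correlation. Of the 9 genes around MET, 8 fell on each day, on either adjustment, and 0, 0 and 1 rose (adjusted p of 0.000332, 0.000363 and 0.000878, and adjusted p = 0.4, 0.415 and 0.367 with an estimated correlation). Of 17 alveolar and lung lineage genes, 10 rose and 1 fell on day 28, on either adjustment, including MUC1 (2.95) and ABCA3 (2.48). The adjusted p was 0.0313 on day 28, and adjusted p = 0.4 with an estimated correlation; it was 0.0576 without day 28 replicate 1, 0.0861 without day 0 replicate 2, and 0.0733 and 0.0957 on days 35 and 56. Antigen presentation genes rose in 14 of 20 cases on day 56 and fell in 3, on either adjustment, with HLA-B up by 2.49 (1.64 with the trends removed) and HLA-E by 1.87. The adjusted p was 0.0309, adjusted p = 0.484 with an estimated correlation, and 0.0544 without day 0 replicate 2. The BCL2 family was not called (adjusted p = 0.0957 on day 56), with 7 of 16 members higher and 2 lower (8 and 2 adjusted over the list alone); BCL2L11 was at 144 ± 15.5 against 18.1 ± 1.4 CPM and HRK at 27.5 ± 1.51 against 0.442 ± 0.117 CPM.

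**Figure D3:**
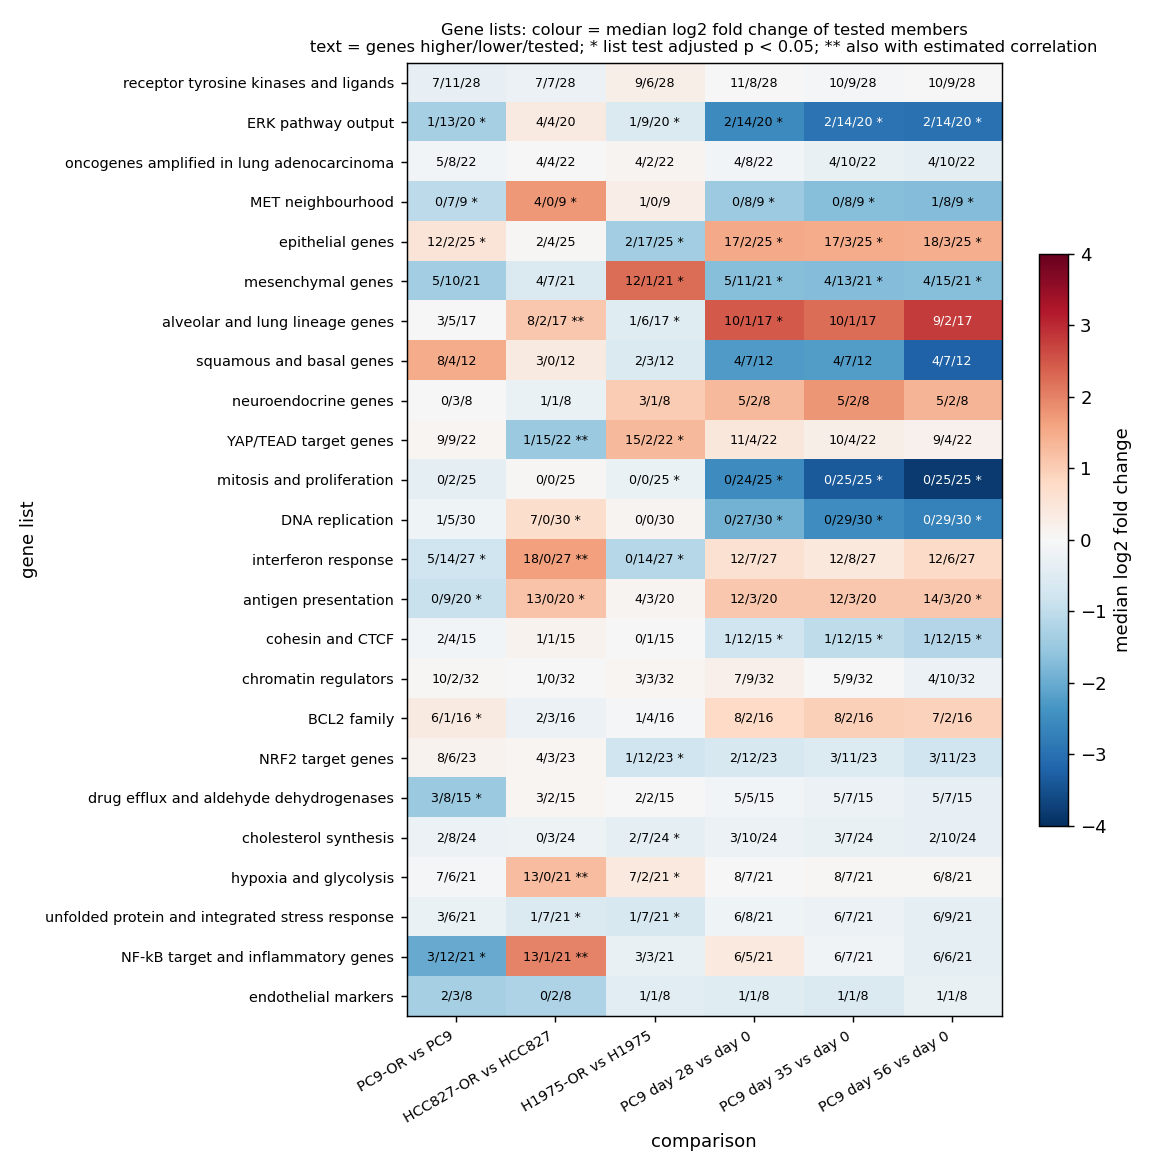
Gene lists (y axis) in 6 comparisons (x axis); colour is the median fitted log2 fold change of the tested members, text gives members higher, lower and tested, 1 star an adjusted p under 0.05 and 2 stars also with an estimated correlation. The mitosis list is lower in 24 or 25 of 25 members at the 3 time points and in 2 of 25 in PC9-OR.

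Between the time points under drug, edgeR called 0 genes in each of the 3 comparisons, while 568 genes (day 35 against 28), 543 (day 56 against 35) and 1756 (day 56 against 28) had an unadjusted p under 0.05. DESeq2 called 0 genes for day 35 against 28, 1 higher and 0 lower for day 56 against 35, and 41 higher and 86 lower for day 56 against 28. Without the filter on low counts, edgeR called 27 higher and 71 lower for day 35 against 28, 5 and 6 for day 56 against 35, and 60 and 235 for day 56 against 28. Fits of the 4 libraries compared called 6 and 15 for day 35 against 28 and 474 and 664 for day 56 against 28. Without day 35 replicate 1, 2 genes were higher and 2 lower on day 35 than on day 28. Windows along the genome gave 11 higher and 2 lower regions on day 28, and 13 and 2 on days 35 and 56. On chromosome 16 from 66841433 to 67198918, 17, 17 and 18 of 20 genes rose. On chromosome 19 from 19668796 to 22608211, 29, 29 and 30 of 50 fell. Changes followed GC content across genes (rank correlations of 0.370, 0.380 and 0.363 by day). The windows were not repeated with that trend removed, so whether it adds to these regions was not tested. Without day 0 replicate 2, 6, 5 and 7 regions passed, and with windows of 10 genes 9 passed on day 56.

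The last question was how far the weeks-long response was shared with PC9-OR, where both sets of cells were under drug and the controls were not. SEMA5A, SIPA1L2 and C5orf38 were each higher at all 3 time points and in PC9-OR, and ZNF738, ZNF43, the chemotaxis regulator ELMO1 and the metallothionein MT1A each lower, in both cases from or to 0 reads except for 1 read of SEMA5A in untreated PC9. Day 56 and PC9-OR shared 2654 higher and 2909 lower genes, against 1200 and 1295 for independent lists, and 670 genes went opposite ways, against 2515. At all 3 time points, 5233 genes were higher and 4686 lower, against 519 and 386 for independent lists; the time points had pairwise correlations of 0.948 to 0.961, against 0.482 to 0.495 in simulated data without any effect, and covariances of 5.74 to 6.01 against 0.231 to 0.232. Across genes, the log2 fold changes of day 56 and PC9-OR had a Pearson correlation of 0.647. Both comparisons use the same untreated libraries, and simulated data without any effect gave a correlation of 0.386, a covariance of 0.146 against 3.63 observed, and 0 shared calls. The simulations gave each gene the same spread in every group. Untreated PC9 replicate 1 had a mean correlation of 0.954 with its group, against 0.990 to 0.991 in PC9-OR. Shared controls may therefore add more than was simulated, and few calls can arise without any effect. With untreated replicate 3 alone as control of PC9-OR and replicates 1 and 2 as control of day 56, 1600 genes were higher and 1909 lower in both, against 798 and 924 for independent lists, and 701 went opposite ways, with a correlation of 0.545 and a covariance of 3.17. The lone control of PC9-OR is assumed there to vary like the other groups.

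The remaining gene lists were not called in any of the 6 comparisons with untreated cells. Receptor tyrosine kinases and ligands (28 tested) had 7 higher and 11 lower members in PC9-OR, 7 and 7 in HCC827-OR, 9 and 6 in H1975-OR and 10 and 9 on day 56; FGFR2 was 866-fold higher in PC9-OR (counting interval 239 to 7161) and at least 999-fold on day 56. Oncogenes amplified in lung adenocarcinoma (22 tested) had 5 and 8, 4 and 4, 4 and 2, and 4 and 10. Squamous and basal genes (12 tested) had 8 and 4, 3 and 0, 2 and 3, and 4 and 7. Neuroendocrine genes (8 tested) had 0 and 3, 1 and 1, 3 and 1, and 5 and 2. Chromatin regulators (32 tested) had 10 and 2, 1 and 0, 3 and 3, and 4 and 10. Endothelial markers (8 tested) had 2 and 3, 0 and 2, 1 and 1, and 1 and 1. Adjusted over the list alone, these counts differed by at most 2 genes, and the smallest adjusted p of these lists in the 4 comparisons was 0.0924, for squamous and basal genes in PC9-OR. Of the fibroblast and blood cell markers, 4 and 3 genes were tested, too few for a list test; 1 fibroblast marker rose and 1 fell in PC9-OR, 0 changed in HCC827-OR and 3 rose in H1975-OR, and 2 blood cell markers fell in PC9-OR with 0 changed in the other resistant lines.

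Fitted changes of genes without reads depend on the prior count, so list medians were also taken with such genes at their bound. In HCC827-OR the median of the genes around MET was 1.72 fitted and 1.13 at the bound, and that of NF-kB target and inflammatory genes 1.999 and 1.51. Median, mean and test differed in sign for 5, 6 and 5 lists in PC9-OR, HCC827-OR and H1975-OR and for 4 on each day, none of them called. These were alveolar, neuroendocrine, YAP/TEAD, NRF2 and hypoxia genes in PC9-OR; receptor tyrosine kinase, epithelial, neuroendocrine, chromatin, BCL2 family and NRF2 genes in HCC827-OR; and DNA replication, antigen presentation, cohesin, efflux and endothelial genes in H1975-OR. In the time course they were receptor tyrosine kinase and efflux genes on each day, chromatin genes on days 28 and 35, hypoxia genes on day 28, YAP/TEAD genes on days 35 and 56, and NF-kB genes on day 56.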

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

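Chosen only after the result was seen were the tests of another cell line, of gains of gene copies on chromosomes 3, 20, 22 and around MET, of sequencing depth, and those with GC and length trends removed.

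The change from untreated parent to resistant cells under drug differed between lines by a test of the difference itself. It differed for 6205 genes between HCC827 and PC9, 6687 between H1975 and PC9, and 3932 between HCC827 and H1975. For MET the difference in log2 fold change was 6.74 (HCC827 against PC9), 4.29 (H1975 against PC9) and 2.46 (HCC827 against H1975). For AXL it was 3.85, 14.33 and -10.47 in the same order. For METTL7A it was -5.68 between HCC827 and PC9 and -6.53 between HCC827 and H1975, and for EGFR -1.32 between HCC827 and H1975.

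Between HCC827 and PC9, NF-kB target and inflammatory genes differed by a median of 2.91 (2.79 with genes without reads at their bound; adjusted p = 0.0115 with an estimated correlation). Between HCC827 and H1975, the median difference was -4.05 for mesenchymal genes (-4.07 at the bound), 1.22 for alveolar and lung lineage genes (1.12), -2.36 for YAP/TEAD target genes (-2.36), 2.78 for interferon response genes (2.83), 0.79 for NRF2 target genes and 2.34 for NF-kB target and inflammatory genes (1.80). These 6 passed with adjusted p of 0.0152 to 0.0498 with an estimated correlation.

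The libraries under drug were far from untreated PC9, with 11776 genes changed on day 56. Another cell line under the treated labels is argued against: of 22 genes absent from untreated PC9 and present in every HCC827 and H1975 library, 16 stayed under 1 CPM in every time-course library and 19 in PC9-OR. With each library's trends in GC content and transcript length removed, 11856 genes changed, and 4846 of the 6171 higher and 4663 of the 5605 lower genes kept their call, which argues against those trends as the whole cause. The rank correlation of change with GC content was 0.363, and the removal changed the balance to 5759 higher and 6097 lower, so a part of the change may follow these trends. The drug, the biological explanation that the design gives, stays open as untested. No untreated PC9 sample was labelled with a later day, so the drug cannot be told apart from weeks in culture. The labels also do not say whether untreated and treated libraries were prepared together, so a difference in preparation stays open too.

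Runs of neighbouring genes were higher in resistant lines. Removing the GC and length trends left a median of 1.65 on chromosome 22 in PC9-OR, against 1.86, which argues against those trends as the whole cause. Of the genes with at least 5 CPM in the untreated line, 89.7% (26 of 29), 87.5% (7 of 8) and 92.3% (60 of 65) were higher in the runs on chromosomes 3, 20 and 22 in PC9-OR and 66.7% (6 of 9) around MET in HCC827-OR, but the runs were chosen for being higher in these comparisons, so the shares give a gain of gene copies no support. Flank medians were -0.00 and 0.25 on chromosome 3, 0.31 and 0.55 on chromosome 20, 0.06 on the right of chromosome 22 and 0.69 and -0.37 around MET, and on chromosome 3 HRH1 (-3.32), ATG7 (0.46) and VGLL4 (0.62), named after their values were seen, lay between SEC13 (2.36) and TAMM41 (3.50), next to which TIMP4 was lower (-2.21). On day 56, which shares controls with PC9-OR, 58.5% of the 65 genes on chromosome 22 were higher, with a median of 0.80. For all genes at this level these were 26.8% and -0.22. Day 56 changes also followed GC content (rank correlation 0.363). The day 56 values were not repeated with that trend removed, so it stays open there too. A gain of gene copies and shared regulation of neighbouring genes both stay open, since no DNA was measured.

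Untreated PC9 replicate 1 had the fewest genes with reads, 19702. Its total of 26.1 (in units of 1e6 counts) was the highest of the 3 untreated PC9 libraries, which argues against sequencing depth. Among genes predicted at 5 to 10 reads from replicates 2 and 3 together, 36.1% had 0 reads in replicate 1. Replicates 2 and 3, each predicted from the other alone, had 11.7% and 9.45%. Counting error alone would give 0.13%, 0.25% and 0.11% in replicates 1, 2 and 3, so all 3 were above it. Few distinct molecules in replicate 1 may be the cause, but the share did not reach the bound set beforehand. No biological explanation was tested. The 6 PC9 and PC9-OR libraries make 10 splits, too few for a share under 0.05: the real split, 1 of the 10, gave 8864 genes changed and the highest other split 0.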

How the results depend on the processing

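Tests chosen only after the data were seen were those with all 3 untreated PC9 libraries as control of the time course, with untreated replicate 3 alone as control of PC9-OR, and with the GC and length trends removed. A sign change counts as reversed where the value with or without the alternative passed its test, and counts of genes were held to a factor of 1.5. The cause was not tested for any value below unless stated.

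RLE size factors within edgeR moved no median log2 fold change of all genes by over 0.1 (day 56: 0.06 to 0.10). Most named genes were picked by their change or adjusted p in these same comparisons. Kept calls among them were therefore likely beforehand and do not stand for all called genes. Of the values for named genes, 1095 kept their direction and side of the threshold with RLE size factors, 1 newly passed and 2 no longer did. With the DESeq2 Wald test these were 1026, 13 and 30, with adjusted p missing and left out for 11 named genes in HCC827-OR and 18 in H1975-OR. Without a filter they were 1054, 31 and 13, with only the compared libraries 989, 23 and 86, with the GC and length trends removed 386, 4 and 5, with all 3 untreated PC9 libraries 521, 5 and 6, and with 1 library left out 4515, 28 and 274, while 1 changed direction in H1975-OR (-0.64 without H1975-OR replicate 1 and 1.76 without replicate 2). With untreated replicate 3 alone as control of PC9-OR they were 195, 1 and 17, with 2694 genes higher and 3435 lower in PC9-OR and 1600 higher and 1909 lower both there and on day 56, against 2654 and 2909. Replicate numbers did not pair the samples (correlations of residuals from -0.101 to 0.102); a replicate block gave 1073, 5 and 20, and ended the calls of the interferon response and BCL2 family lists in PC9-OR (adjusted p = 0.068 and 0.0544).

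Without a filter on low counts, 27 genes were higher and 71 lower on day 35 than on day 28, 5 and 6 on day 56 than on day 35, and 60 and 235 on day 56 than on day 28, against 0 in each. The DESeq2 Wald test gave 1 higher on day 56 than on day 35, 41 higher and 86 lower on day 56 than on day 28, and 81 higher in all 3 resistant lines against 52. With only the libraries compared, where fewer libraries set the spread, 2697 genes were higher in PC9-OR, 4395 higher and 4627 lower in HCC827-OR, and 901 and 1212 in H1975-OR. The same fits gave 3030 and 3055 on day 28, 3304 and 3220 on day 35, 3505 and 3291 on day 56, 6 and 15 on day 35 against day 28, and 474 and 664 on day 56 against day 28. Of all higher and lower calls, they kept 65.8% and 75.7% in PC9-OR and 42.2% and 53.0% in H1975-OR. In HCC827-OR 99.5% of each were kept, and in the time course against day 0 51.2% to 58.7%.

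With an estimated correlation, 0 lists were called in PC9-OR against 8, 5 in HCC827-OR against 9, 0 in H1975-OR against 11, and 0 on days 28, 35 and 56 against 8, 7 and 8. Fry, which does not compare a list with other genes, called 17 in PC9-OR and 19, 16 and 18 on days 28, 35 and 56; for drug efflux and aldehyde dehydrogenases on day 28 it gave the opposite direction (adjusted p = 0.0357, against 0.923 by camera). Windows of 40 genes gave 31 regions in PC9-OR against 18; windows of 10 genes gave 4 in H1975-OR against 13 and 9 on day 56 against 15.

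Leaving out 1 library can leave 1 sample in a group, which is then assumed to vary like the other groups. Day 35 against day 28 then had 0 to 2 genes higher and 0 to 2 lower. HCC827-OR had 670 to 831 higher and 803 to 1189 lower, H1975-OR 1018 to 2107 and 1363 to 2194, all 3 lines 31 to 55 and 46 to 85, and the resistance effect was lower in HCC827 than in H1975 for 1360 to 2385 genes. Regions numbered 6 to 13 in H1975-OR, 6 to 11 in HCC827-OR, 6 to 16 on day 28, 5 to 14 on day 35 and 7 to 14 on day 56, the lowest on each day without day 0 replicate 2. Lists called in PC9-OR numbered 5 to 9, 5 without PC9 replicate 3. In H1975-OR, the mitosis and proliferation list had an adjusted p of 1.06e-18 to 0.0277 and was in the opposite direction without H1975-OR replicate 2 (0.00209); the DNA replication list had 1.05e-11 to 0.446, and was in the opposite direction without the same library (1.96e-06). Without PC9 replicate 1, the library with the fewest genes, PC9-OR had 4427 genes higher and 5159 lower. With n = 2, changes near 2-fold were often missed in simulated data (19.6% recovered for H1975-OR). Far fewer genes were changed there than the 20.3% called in H1975-OR, so the share missed in the real data may differ.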

Other observations

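The zinc finger genes on chromosome 19 were examined as a set only after the run of lower genes there had been seen. The set holds symbols beginning with ZNF, antisense and pseudogene symbols included. Zinc finger genes with other symbols count among the other genes of the chromosome. Of 257 tested, 113 were lower and 39 higher in PC9-OR (44.0% lower), against 23.1% lower among all tested genes and 12.8% among the other 1252 tested genes of the chromosome. On days 28, 35 and 56, 109, 122 and 117 were lower and 40, 40 and 46 higher. The share lower was 42.4%, 47.5% and 45.5% by day, against 25.7%, 26.8% and 26.9% among all tested genes. Of the zinc finger genes, 88 were lower both on day 56 and in PC9-OR. In HCC827-OR and H1975-OR 4 were lower and 12 higher in each. Reads shared between zinc finger genes were not examined, nor was the GC content of the set. Changes followed GC content across all genes in PC9-OR (rank correlation 0.179) and on each day (0.363 to 0.380).

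Mitochondrial ribosomal RNA made up 1.88% to 1.997% of the counts in PC9-OR and 0.643% to 1.04% in untreated PC9. All mitochondrial transcripts made up 0.807% and 0.781% of the counts in HCC827-OR and 1.96% and 1.94% in HCC827.

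Histone transcripts (symbols beginning HIST1H to HIST4H) made up 0.0374% to 0.061% of the counts in the 6 time-course libraries under drug, 0.0209% to 0.0218% in untreated PC9 and 0.0081% to 0.00876% in PC9-OR. The share was 0.0353% and 0.0346% in H1975, 0.0201% and 0.0386% in H1975-OR, 0.0179% and 0.0163% in HCC827, and 0.0151% and 0.0152% in HCC827-OR. As poly-A RNA was sequenced, these shares cover only histone transcripts captured in that way and do not measure all histone RNA.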
